A study of Mus musculus with 4 samples.

How the data were processed

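Gene expression was measured in the hearts of 4 male mice on Clariom S Mouse arrays, which read each gene through a set of short oligonucleotides summarized to 1 value per transcript cluster, called a probe here. Myocardial infarction had been induced by tying off the left coronary artery at 8 weeks of age, and the whole hearts were collected 3 months later, per the labels. The labels place 2 hearts in the control group (Ctrl-MI, genotype Tcf21iCre/Tomato) and 2 in the transgenic group (TTg-MI, genotype Tcf21iCre/Tomato/MGTH2A). The series' design text describes the 2 hearts of each group as independent biological replicates.

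The deposited values were taken as log2 expression values. The log base is not given in the sources used here and was inferred from their range of about 4 to 20 on each array. The arrays had been processed in Affymetrix Expression Console 1.4, per the submitters' processing notes. The normalization and summarization methods, the annotation version and the genome build were not given in the sources used here. The array medians and quartiles were near each other without being identical. The values were used as deposited, with no further normalization or filter. For arrays no read depth applies, and the number of arrays limits the precision: each difference rests on 2 residual degrees of freedom, to which the moderated variance model added 3.56.

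Probes were named from the platform's annotation table. Of the 22206 probes, 19572 had 1 gene symbol, 0 had several and 2634 were unnamed here. Updating through Entrez identifiers changed 0 symbols, and 19505 different symbols were present. The reference gene table belonged to assembly GRCm38.p6 and was used only for names and for the order of neighbouring genes. As no build was named for the array, no coordinates are given.

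The comparison was TTg-MI against Ctrl-MI, and every log2 difference is the TTg-MI mean minus the Ctrl-MI mean. Each probe was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with default settings, two-sided), with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. With 2 arrays against 2, an exact two-sided permutation test of a single gene cannot give a p below 0.333, so the tests here rest on the variance that limma shares across probes. Gene lists were tested with camera in limma, which asks whether the members of a list moved more in 1 direction than all other named genes. It was run on 1 probe per symbol, the one with the highest average, with a preset correlation between genes of 0.01, and adjusted by Benjamini-Hochberg over all lists with at least 3 measured members. Members of a list were also adjusted over the list alone. The 4 factor genes of the transgene and Tcf21 formed a separate family of 5 genes.

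The gene lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. There were 16 lists of cell type markers and 19 lists of pathways or functions, and 423 of the 462 members written matched a named probe. The remaining members were not analysed here. The erythroid list had fewer measured members than the minimum and was not tested, which left 34 lists. Lists share members: Fn1, Col8a1, Lox and Postn belong to both the matrix and activated fibroblast lists, Ltbp2 to the activated fibroblast and TGF-beta lists, and Nppa to the atrial and fetal lists. The cardiomyocyte and sarcomere lists also overlap, as do the endothelial and angiogenesis lists.

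Genes were named by a fixed rule. The factor genes and Tcf21 were always named. In each direction, 10 probes were named among those past the adjusted threshold without overlap of the groups' arrays, with 1 established symbol and a higher group mean at or above the median of all probes. Where fewer passed, the remaining places went to the smallest unadjusted p among probes differing at least 1.5-fold. Up to 4 members with the smallest p were named for a list that passed camera, and up to 2 for any other list. Genes given a difference outside this rule are stated as chosen after their values were seen. Others outside it are named only for list membership, their place in the measured range or a pass in an alternative fit.

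The alternatives were quantile normalization, median centring, a filter on dim probes, eBayes with an intensity trend and robust prior, the replicate number as a block, leaving out each array in turn, a relaxed adjusted threshold of 0.1, an unadjusted threshold with a 1.5-fold minimum, an ordinary linear model without moderation, 1 probe per symbol, camera with an estimated correlation, camera on ranks, fry, and the mean of a gene's probes. fry is a rotation test of whether a list's genes move on balance one way (directional) or in either direction (mixed), without comparing them to other genes. A fit without 1 array assumes that the lone array of its group varies like the arrays of the other group. The removal of atrial genes and the other groupings of the 4 arrays were added after the data had been seen.

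The procedures were tested on simulated data of 2 against 2 arrays with 22206 probes, 200 of them changed, in 10 simulations. limma recovered 4.33% of probes changed 2-fold, 83.0% of those changed 4-fold and 95.5% of those changed 8-fold, and 5.00% of the called probes were false. The noise of these probes was drawn independently from the variance model that limma fitted to the real data. Shifts shared by many genes of an array, as on Ctrl-MI replicate 1, were absent, so these shares may not hold for the real arrays. For simulated lists of 15 genes, camera with the preset correlation called 0% to 0.690% of unchanged lists whose genes varied independently, over the settings for the shifted lists beside them. It called 27.2% to 35.2% of unchanged lists whose genes shared a correlation of 0.4. With an estimated correlation camera called 0% of the lists shifted by 0.5 or 1 log2 units. Of those shifted by 1.5 it called 40% where genes varied independently and 0% where they shared the correlation of 0.4. The shifts of 1 and 1.5 were added after the data had been seen.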

Results

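The transcriptomes of 4 infarcted mouse hearts were compared, 2 from control mice (Ctrl-MI) and 2 from mice that also carried the MGTH2A transgene (TTg-MI). Both groups carried Tcf21iCre, a Cre recombinase under Tcf21, a transcription factor gene of cardiac fibroblasts, together with a Tomato reporter. MGTH2A is known in the field as a single construct for the cardiac transcription factors Mef2c, Gata4, Tbx5 and Hand2, which can turn cultured fibroblasts into cells resembling cardiomyocytes. The study asked what this reprogramming does in fibroblasts of the chronically infarcted heart, 3 months after the coronary artery was tied off. The labels give the whole heart as the source of RNA, a mixture of muscle, fibroblasts, vessels and blood cells, although Ctrl-MI replicate 2 held little signal of some atrial muscle genes.

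Array medians lay between 6.55 and 6.62 log2 units. Pearson correlations between arrays were taken across probes, which are not independent replicates. They ran from 0.977 for Ctrl-MI replicate 1 with TTg-MI replicate 2 to 0.991 for the TTg-MI pair. Ctrl-MI replicate 2 correlated at 0.991 with TTg-MI replicate 1 and 0.989 with TTg-MI replicate 2, but at 0.987 with Ctrl-MI replicate 1. The Ctrl-MI arrays thus did not group together. The first principal component held 58.4% of the variance and set Ctrl-MI replicate 1 apart, with a score of -47.1 against -1.29 for Ctrl-MI replicate 2, 16.5 for TTg-MI replicate 1 and 31.9 for TTg-MI replicate 2. Between 40 and 43 probes per array lay within 1 log2 unit of that array's highest value of about 19.9. These include heavily expressed muscle genes such as Myh6, an alpha myosin heavy chain, at 19.75 ± 0.01 in TTg-MI (SD, n = 2). The calcium pump gene Atp2a2 and the genes Mb and Fabp3 held the highest value of every array. Some genes picked for naming lay under the arrays' lower quartiles of 5.41 to 5.48, where they were not shown to be above background. These were Bmp10 and Retnlg on both Ctrl-MI arrays, Ccr2, Cd3g and Ms4a1 on both TTg-MI arrays, Gabra3 and Cdh19 on TTg-MI replicate 1, and Il1rn, S100a8 and Ucp1 on all 4, so that no difference is given for these 3. Where arrays of only 1 group lay so low, or within 1 log2 unit of the highest value, the difference is read as a lower limit of its size.

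Of the transgene's factor genes, Tbx5 and Mef2c were higher in TTg-MI hearts. Tbx5, a T-box factor of the atria and conduction system, rose from 7.75 ± 0.19 in Ctrl-MI to 10.20 ± 0.67 in TTg-MI (log2, SD, n = 2 each), a 5.46-fold difference. Mef2c, a MADS-box factor of heart muscle, rose from 12.84 ± 0.24 to 14.99 ± 1.44, a 4.44-fold difference, with 16.01 on TTg-MI replicate 1 and 13.97 on TTg-MI replicate 2. Gata4 stood at 13.56 ± 0.25 and 13.72 ± 0.49, and Hand2 at 8.66 ± 0.60 and 9.44 ± 0.71. Tcf21, whose promoter drives the Cre in both groups, fell from 8.63 ± 0.47 to 7.26 ± 0.00.

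In limma with Benjamini-Hochberg adjustment over these 5 genes alone, Tbx5 (log2 difference 2.45, SE 0.33, adjusted p = 0.00221), Tcf21 (-1.37, SE 0.25, adjusted p = 0.00464) and Mef2c (2.15, SE 0.64, adjusted p = 0.0282) passed. Gata4 (0.16, SE 0.27, adjusted p = 0.587) and Hand2 (0.78, SE 0.42, adjusted p = 0.149) did not. Thus 3 of 5 passed when adjusted over the list alone and 0 when adjusted over all 22206 probes, where limma gave Tbx5 an adjusted p of 0.530. The Mef2c difference was 1.13 without TTg-MI replicate 1 and lost its pass without Ctrl-MI replicate 1 (limma with Benjamini-Hochberg, adjusted p = 0.0561 over the 5 genes, within a range of 1.98e-04 to 0.0561 as single arrays were left out). The Hand2 difference was 1.20 without Ctrl-MI replicate 1, 0.35 without Ctrl-MI replicate 2, 0.27 without TTg-MI replicate 1 and 1.28 without TTg-MI replicate 2. Whether the probes of the factor genes also read the transgene's transcript was not analysed here.

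As a list, the 4 factor genes passed camera with a median log2 difference of 1.46 (adjusted p = 8.34e-04, Benjamini-Hochberg; adjusted p = 0.589 with an estimated correlation). Of the 4, 2 passed when adjusted over the list alone and 0 over all genes. The arrays of the groups overlapped for Gata4 and Hand2, and the Gata4 difference was -0.016 without Ctrl-MI replicate 1 and -0.186 without TTg-MI replicate 1. Without TTg-MI replicate 1 the list's median was 0.70. The members passing over the list alone numbered 1 without Ctrl-MI replicate 1, 1 without Ctrl-MI replicate 2 and 3 without TTg-MI replicate 2.

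**Figure D1:**
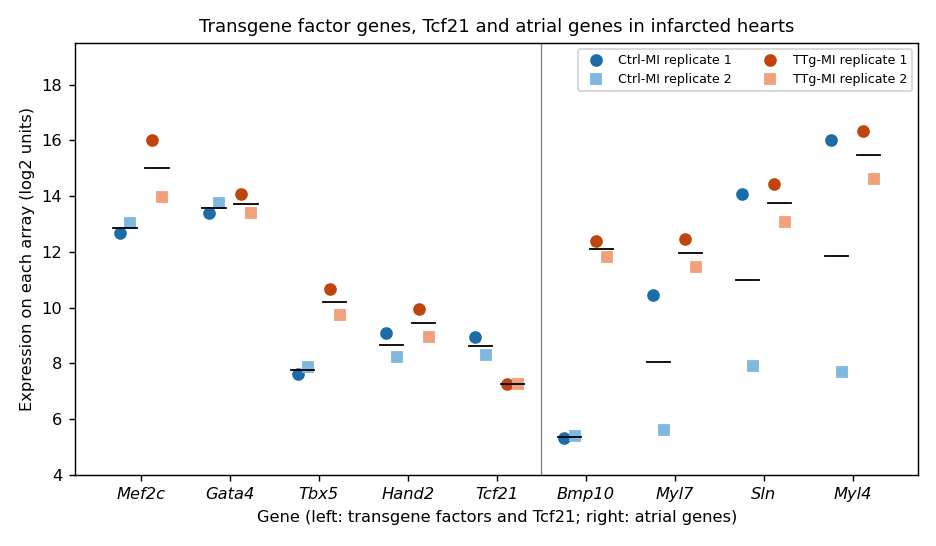
Expression of the transgene's factor genes, Tcf21 and 4 atrial genes on each array, in log2 units. Points are single arrays and black lines are group means (n = 2). Bmp10 lies at 5.31 and 5.40 in Ctrl-MI and at 12.38 and 11.82 in TTg-MI, while Myl4 and Sln on Ctrl-MI replicate 1 lie within the range of the TTg-MI arrays.

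Bmp10, a growth factor gene of the atrial muscle, was the 1 gene that passed limma over all probes. It stood at 5.35 ± 0.06 in Ctrl-MI and 12.10 ± 0.39 in TTg-MI (log2, SD, n = 2 each), a log2 difference of 6.75 (SE 0.22), with both TTg-MI arrays above both Ctrl-MI arrays. As the Ctrl-MI values lay under the lower quartiles of those arrays (5.48 and 5.41), the difference is read as a lower limit. Its adjusted p in limma with Benjamini-Hochberg was 0.00489, and the next smallest of any probe was 0.134. Leaving out single arrays gave differences of 6.47 to 7.03 and adjusted p in limma of 0.00824 to 0.0239. An ordinary linear model without limma's moderation called 0 genes after Benjamini-Hochberg adjustment and gave 1241 probes at an unadjusted p under 0.05.

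In all, 1833 probes had an unadjusted limma p under 0.05, 707 higher and 1126 lower in TTg-MI, where 1110 would be due to chance. Both TTg-MI arrays lay above both Ctrl-MI arrays for 4311 probes and below them for 4157, together 38.1% of probes against the 33.3% that chance gives. Without Ctrl-MI replicate 2 the same limma test called 332 genes and gave 3275 probes at an unadjusted p under 0.05. It called 2 without Ctrl-MI replicate 1, Bmp10 and Pde7b, the latter chosen after its value was seen, and 862 probes had an unadjusted p under 0.05 without TTg-MI replicate 2. Among the fits that left out 1 array, 41 of the 119 named genes passed only without Ctrl-MI replicate 2. The differences of 61 of the 119 moved by more than 1.5 times in at least 1 of these fits, 45 without Ctrl-MI replicate 1, 25 without Ctrl-MI replicate 2, 15 without TTg-MI replicate 1 and 19 without TTg-MI replicate 2.

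None of the other genes named by size and p passed the adjustment. The higher ones were Lgals4, a galectin of epithelia (log2 difference 1.63, SE 0.17), Slc16a7, a monocarboxylate transporter (1.67, SE 0.21), Antxr2 (1.24, SE 0.15), Stard10 (1.35, SE 0.18) and Kpna2, an importin (2.83-fold). Reep1 (1.11, SE 0.18), Zfp931 (1.07, SE 0.17) and Apobec3, a cytidine deaminase active against retroviruses (0.97, SE 0.15), followed. The lower ones were led by Resf1, a factor in retroelement silencing (-3.69, SE 0.43), Jchain, the joining chain of secreted antibodies (-2.63, SE 0.18), Gnao1, a G protein subunit (-1.99, SE 0.16), and Cd300ld, a myeloid surface receptor (-1.88, SE 0.18). Bcl2, an inhibitor of apoptosis (-1.77, SE 0.24), Gabra3 (-1.60, SE 0.16), Cmip (-1.47, SE 0.20), Eln, which encodes elastin (-1.37, SE 0.20), Uck2 (-1.26, SE 0.17) and Tmem45a (-1.19, SE 0.16) were also lower. Adjusted p in limma with Benjamini-Hochberg ran from 0.134 for Jchain to 0.530 for Eln. Jchain, Resf1 and Gabra3 passed with an intensity trend and robust prior in eBayes, at adjusted p of 0.00710, 0.0477 and 0.0477, and over all alternatives the adjusted p for Jchain ranged from 0.00710 to 0.329.

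Of the 34 gene lists, 18 passed camera with Benjamini-Hochberg adjustment, 5 with higher and 13 with lower members in TTg-MI. By this test matrix, fibroblast, macrophage and fetal muscle genes were lower, and atrial, calcium handling and mitochondrial genes were higher. The test assumes a correlation of 0.01, while those estimated for the 18 lists ran from 0.0961 for cytokines to 0.911 for MHC class II. At a simulated correlation of 0.4 it called 27.2% to 35.2% of unchanged lists. For 15 of the 18, the list scores of the TTg-MI arrays did not overlap those of the Ctrl-MI arrays. Counts of higher or lower members given below compare group means, and the arrays of single members often overlapped. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.589, and fry called 0 lists in the directional and 1 in the mixed test. Leaving out each array in turn, 14 of the 18 lists kept their call and direction in every such fit, and 15 kept the call without Ctrl-MI replicate 1. Single members were less settled, and the number passing changed widely as single arrays were left out. Adjusted over the list alone, 29 memberships in the 18 lists passed limma with all arrays. Lox and Ltbp2 count more than once among them, as they passed in each of their lists.

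**Figure D2:**
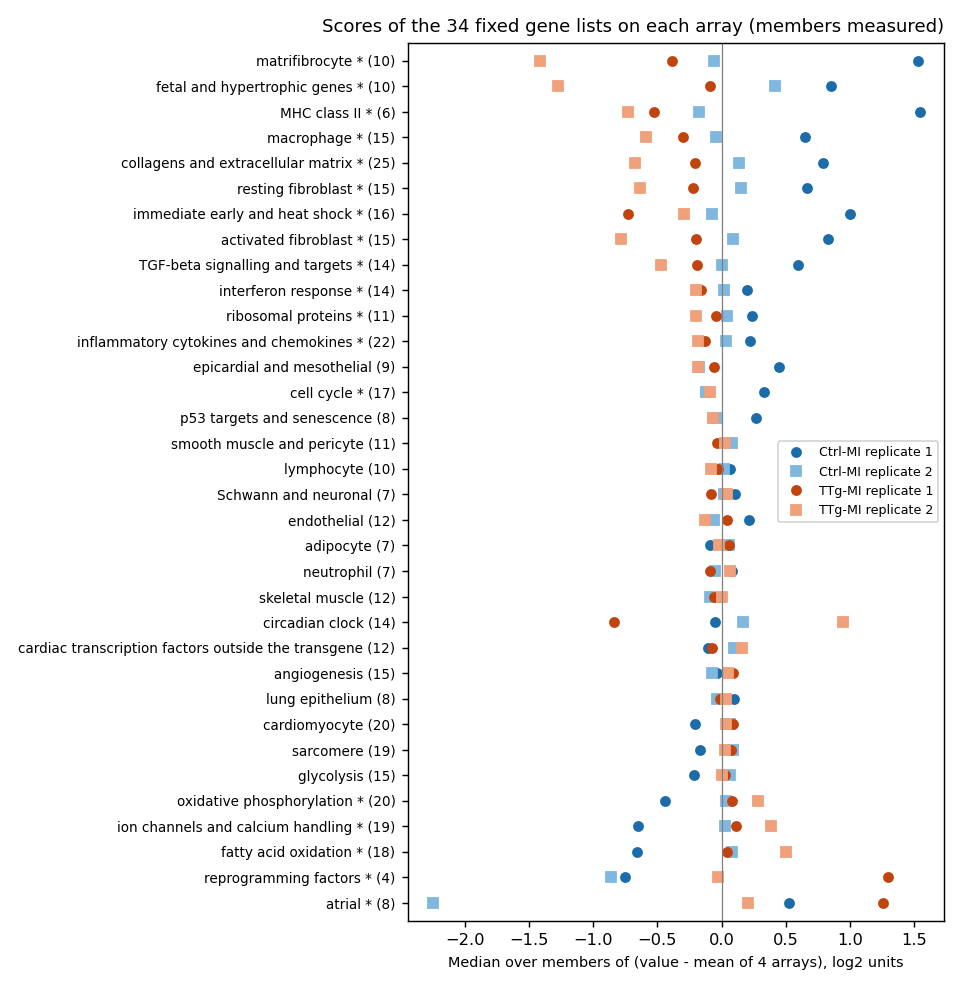
Score of each of the 34 gene lists on each array, as the median over members of the log2 value minus the gene's mean of the 4 arrays. Asterisks mark the 18 lists past the camera threshold and numbers in brackets are measured members. Ctrl-MI replicate 1 has the highest score of the 4 arrays in the collagen and matrix list, at 0.79 against 0.13 for Ctrl-MI replicate 2, -0.21 for TTg-MI replicate 1 and -0.68 for TTg-MI replicate 2.

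Genes of the extracellular matrix were lower in TTg-MI hearts. Of 25 measured collagen and matrix genes, 23 were lower, with a median log2 difference of -0.83, which is 1.77-fold lower. Elastin (Eln, -1.37, SE 0.20), versican (Vcan, -1.57, SE 0.25), the cross-linking enzyme Lox (-1.79, SE 0.36) and thrombospondin 1 (Thbs1, -2.54, SE 0.58) led the list. The fibrillar collagens Col1a1 and Col3a1 differed by -0.80 (SE 0.32) and -1.67 (SE 0.65). The list passed camera at an adjusted p of 7.17e-15 with Benjamini-Hochberg (adjusted p = 0.589 with an estimated correlation). In limma, 6 members, all lower, passed when adjusted over the list alone and 0 over all genes. For 22 of the 25 both TTg-MI arrays lay below both Ctrl-MI arrays, where chance gives 16.7% for a single gene. The same held for 4157 of all 22206 probes. The 25 genes share the same 4 arrays, with an estimated correlation of 0.45, so they are not independent draws. The Thbs1 difference was -1.62 without Ctrl-MI replicate 1. The members passing over the list alone numbered 4, 20, 7 and 0 without Ctrl-MI replicate 1, Ctrl-MI replicate 2, TTg-MI replicate 1 and TTg-MI replicate 2.

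Markers of fibroblasts moved with the matrix. Of 15 resting fibroblast markers 13 were lower, with a median of -0.81, led by Tcf21 (-1.37, SE 0.25), the matrix protein fibulin 1 (Fbln1, -2.21, SE 0.45), gelsolin (Gsn, -1.02, SE 0.24) and Htra3 (-0.64, SE 0.16). Of 15 activated fibroblast markers 12 were lower, with a median of -0.79, including the latent TGF-beta binding protein Ltbp2 (-1.25, SE 0.21), Lox and Ddah1 (-1.40, SE 0.28). Acta2, the smooth muscle actin of contractile fibroblasts and vessels, went the other way, from 13.44 ± 0.49 to 14.70 ± 0.05 (1.26, SE 0.26). Of 10 matrifibrocyte markers, genes of scar fibroblasts that resemble cartilage, 9 were lower with a median of -1.67, among them Comp (-3.48, SE 0.95), Sfrp2 (-3.31, SE 1.20), Fmod (-2.71, SE 0.91) and Ecrg4 (-2.12, SE 0.50). Without Ctrl-MI replicate 1 these 4 differed by -2.08, -1.79, -1.25 and -1.39, and without Ctrl-MI replicate 2 Fmod differed by -4.17. Without TTg-MI replicate 2 Sfrp2 differed by -2.04.

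The resting, activated and matrifibrocyte lists passed camera with Benjamini-Hochberg at adjusted p of 4.73e-08, 3.78e-06 and 3.74e-05, each with adjusted p = 0.589 with an estimated correlation. In limma, 5 resting markers passed when adjusted over the list alone, as did 6 activated markers, 5 lower and Acta2 higher, and 0 matrifibrocyte markers, of which 5 had an unadjusted p under 0.05. Over all genes 0 of each passed. The activated fibroblast median was -0.43 without Ctrl-MI replicate 1, -1.45 without Ctrl-MI replicate 2 and -1.21 without TTg-MI replicate 1. The matrifibrocyte median was -0.75 without Ctrl-MI replicate 1. Over the list alone, 0 markers of the 3 lists passed without TTg-MI replicate 2. Without Ctrl-MI replicate 1, Ctrl-MI replicate 2 and TTg-MI replicate 1 the passing markers numbered 2, 11 and 7 for resting, 5, 13 and 7 for activated fibroblasts and 3, 8 and 4 for matrifibrocytes.

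TGF-beta ligands, receptors and targets were lower alongside the fibroblast markers, 12 of 14 measured genes, with a median log2 difference of -0.58. The ligand Tgfb2 (-1.54, SE 0.35), the receptor Tgfbr1 (-0.83, SE 0.23), the transcriptional co-repressor Skil (-1.21, SE 0.32) and Ltbp2 had the smallest p. The list passed camera at an adjusted p of 1.84e-05 with Benjamini-Hochberg (adjusted p = 0.589 with an estimated correlation), and 5 members, all lower, passed limma when adjusted over the list alone against 0 over all genes. The median was -0.28 without Ctrl-MI replicate 1 and -0.89 without Ctrl-MI replicate 2, and the Skil difference was -0.73 without Ctrl-MI replicate 1. The members passing over the list alone numbered 3, 9, 0 and 0 without Ctrl-MI replicate 1, Ctrl-MI replicate 2, TTg-MI replicate 1 and TTg-MI replicate 2.

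Macrophage genes had a lower TTg-MI mean for all 15 measured markers, with a median log2 difference of -0.95. No single marker passed limma; the mannose receptor Mrc1 differed by -1.57 (SE 0.41), the lysozyme gene Lyz2 by -1.98 (SE 0.59), Adgre1 by -1.09 (SE 0.36) and the monocyte receptor Ccr2 by -0.46 (SE 0.15), a lower limit. With Ctrl-MI replicate 1 left out the first 3 differed by -0.9974, -1.32 and -0.56, and Lyz2 by -1.29 without TTg-MI replicate 2. The antigen-presenting MHC class II genes were lower for all 6 measured, with a median of -1.35, H2-Aa at -2.02 (SE 0.71), H2-Eb1 at -1.62 (SE 0.61), H2-DMb1 at -1.41 (SE 0.40) and H2-Ab1 at -1.29 (SE 0.72). Without Ctrl-MI replicate 1 these 4 differed by -0.89, -0.65, -0.80 and -0.14, and without Ctrl-MI replicate 2 H2-Aa, H2-Eb1 and H2-Ab1 differed by -3.14, -2.59 and -2.45. Of 22 cytokine and chemokine genes 19 had a lower TTg-MI mean, with a median of -0.28, but 5 of the 22 (Il6, Il1a, Il1rn, Il18 and Nlrp3) lay under the lower quartile of every array. The lower ones included the chemokines Ccl8 (-1.18, SE 0.26) and Ccl3 (-0.57, SE 0.15) and the prostaglandin synthase Ptgs2 (-0.96, SE 0.29). Of 14 interferon response genes 13 were lower, with a median of -0.32, led by Gbp3 (-0.58, SE 0.18), Ifit2 (-0.66, SE 0.23), Bst2 (-0.70, SE 0.29) and Ifit1 (-0.36, SE 0.15). With Ctrl-MI replicate 1 left out, Ptgs2, Ifit2 and Bst2 differed by -0.56, -0.39 and -0.28, and Bst2 by -1.11 without Ctrl-MI replicate 2.

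These 4 lists passed camera with Benjamini-Hochberg at adjusted p of 1.26e-07 for macrophages, 3.67e-04 for MHC class II, 2.02e-05 for cytokines and 1.54e-04 for interferon response, each with adjusted p = 0.589 with an estimated correlation. In limma 0 of their members passed when adjusted over the list alone and 0 over all genes. The numbers at an unadjusted p under 0.05 were 7, 3, 5 and 2, all lower. Both TTg-MI arrays lay below both Ctrl-MI arrays for 10 of 15 macrophage, 3 of 6 MHC class II, 12 of 22 cytokine and 8 of 14 interferon genes. Without Ctrl-MI replicate 1 the medians were -0.45 for macrophages, -0.39 for MHC class II, -0.14 for cytokines and -0.18 for interferon response. Without Ctrl-MI replicate 2 they were -2.23 for MHC class II and -0.42 for cytokines, and 9 macrophage, 6 MHC class II, 8 cytokine and 3 interferon genes then passed over the list alone.

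Genes of the fetal and hypertrophic programme, which heart muscle re-expresses under load, had a lower TTg-MI mean for all 10 measured members, with a median log2 difference of -1.48. Skeletal actin Acta1 fell from 19.28 ± 0.31 to 15.56 ± 2.01 (-3.72, SE 0.87), the beta myosin heavy chain Myh7 from 18.90 ± 0.04 to 17.44 ± 0.44 (-1.46, SE 0.24), Xirp2 by 2.10 (SE 0.51) and Uchl1 by 0.75 (SE 0.18). The natriuretic peptide genes Nppa and Nppb differed by -0.53 (SE 0.35) and -2.34 (SE 1.19) without passing. Nppb, chosen after its values were seen, stood at 17.21 and 15.66 in Ctrl-MI and 15.90 and 12.29 in TTg-MI. Much of its difference rests on TTg-MI replicate 2. Nppa, at -1.06 without TTg-MI replicate 1 and 0.00 without TTg-MI replicate 2, lay near the top of the measured range on 3 of 4 arrays. Acta1 on both Ctrl-MI arrays and Myh7 on Ctrl-MI replicate 1 also lay within 1 log2 unit of the highest value, so their differences are read as lower limits. The list passed camera at an adjusted p of 3.22e-08 with Benjamini-Hochberg (adjusted p = 0.589 with an estimated correlation). The 4 genes Acta1, Myh7, Xirp2 and Uchl1 passed limma when adjusted over the list alone, and 0 passed over all genes. Without TTg-MI replicate 2 the median was -0.82 and the Acta1 difference -2.30. The members passing over the list alone numbered 1, 5, 8 and 3 without Ctrl-MI replicate 1, Ctrl-MI replicate 2, TTg-MI replicate 1 and TTg-MI replicate 2.

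Atrial markers were higher in TTg-MI for 5 of 8 genes, with a median log2 difference of 1.46, and differed widely between the Ctrl-MI hearts. The atrial myosin light chain Myl7 stood at 10.44 and 5.61 in Ctrl-MI and 12.45 and 11.47 in TTg-MI. The atrial light chain Myl4, chosen after its values were seen, stood at 15.99 and 7.70 in Ctrl-MI and 16.34 and 14.61 in TTg-MI. Sarcolipin (Sln), an inhibitor of the calcium pump, stood at 14.07 and 7.90 against 14.42 and 13.06. Ctrl-MI replicate 1 lay above the lower TTg-MI array for Myl4 and Sln and below both TTg-MI arrays for Myl7 and Bmp10. On Ctrl-MI replicate 2 Myl7 lay close to that array's lower quartile of 5.41. With Ctrl-MI replicate 1 left out, Myl7 and Sln differed by 6.34 and 5.84, and without Ctrl-MI replicate 2 by 1.51 and -0.33. The list passed camera at an adjusted p of 0.0486 with Benjamini-Hochberg (adjusted p = 0.658 with an estimated correlation), and 1 member, Bmp10, passed limma when adjusted over the list alone and over all genes.

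The atrial call ended with quantile normalization (adjusted p = 0.0606 in camera with Benjamini-Hochberg), with median centring (0.0558) and on ranks (0.372), while over all alternatives its adjusted p ranged from 1.00e-10 to 0.996. The atrial median was -0.46 without Ctrl-MI replicate 2 (adjusted p = 0.996), 0.94 without TTg-MI replicate 1 (adjusted p = 0.658) and 3.35 without Ctrl-MI replicate 1. The members passing over the list alone numbered 4, 3, 2 and 1 without Ctrl-MI replicate 1, Ctrl-MI replicate 2, TTg-MI replicate 1 and TTg-MI replicate 2.

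Ion channel and calcium handling genes had a median log2 difference of 0.45 over 19 measured members, 7 of which had both TTg-MI arrays above both Ctrl-MI arrays while the others overlapped. Atp2a2, at the highest value of every array, has no measured direction. The inward rectifier channels Kcnj2 (1.64, SE 0.37) and Kcnj3 (1.64, SE 0.37), the sodium-calcium exchanger Slc8a1 (0.87, SE 0.22) and the potassium channel Kcnh2 (1.03, SE 0.36) had the smallest p. Of 18 fatty acid oxidation genes 16 were higher, counting Fabp3 at the arrays' highest value, with a median of 0.49, including Etfdh (0.94, SE 0.37), Hadha (0.72, SE 0.31) and the carnitine carrier Slc25a20 (1.30, SE 0.56). Pdk4, a kinase that restrains glucose oxidation, stood apart at -0.65 (SE 0.16). Of 20 oxidative phosphorylation genes 19 were higher, counting Atp5a1 at the highest value of 3 arrays, with a median of 0.38, led by Sdha (0.71, SE 0.21), Ndufs1 (0.81, SE 0.27), Uqcrfs1 (0.51, SE 0.21) and Uqcrc1 (0.49, SE 0.24). Leaving out Ctrl-MI replicate 1 gave 1.08 for Kcnj3, 0.49 for Kcnh2, 0.38 for Etfdh, 0.31 for Hadha, 0.39 for Slc25a20, 0.51 for Ndufs1, 0.26 for Uqcrfs1 and 0.21 for Uqcrc1. Leaving out Ctrl-MI replicate 2 gave 1.58 for Kcnh2, 1.49 for Etfdh, 1.12 for Hadha, 2.20 for Slc25a20 and 0.78 for Uqcrc1.

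The lists passed camera with Benjamini-Hochberg at adjusted p of 1.02e-05 for ion channels (adjusted p = 0.603 with an estimated correlation), 2.60e-04 for fatty acid oxidation (adjusted p = 0.627 with an estimated correlation) and 3.74e-05 for oxidative phosphorylation (adjusted p = 0.603 with an estimated correlation). In limma 0 members of each passed when adjusted over the list alone and 0 over all genes, and 6, 1 and 2 were higher at an unadjusted p under 0.05. Of the fatty acid oxidation genes 6 of 18 were higher and 1 lower without overlap of the arrays. Of the oxidative phosphorylation genes 7 of 20 were higher and 0 lower in that way. Without Ctrl-MI replicate 1 the medians were 0.05 for ion channels, 0.18 for fatty acid oxidation (adjusted p = 0.472 in camera, within 1.21e-09 to 0.655 over all alternatives) and 0.06 for oxidative phosphorylation (adjusted p = 0.297, within 2.43e-08 to 0.603). Without Ctrl-MI replicate 2 they were 0.81, 0.91 and 0.66, and 12, 15 and 9 members then passed over the list alone. Without TTg-MI replicate 1 the fatty acid median was 0.78, and without TTg-MI replicate 2 it was 0.30 (adjusted p = 0.104) and the ion channel median 0.29. Over the list alone 1 ion channel gene passed without Ctrl-MI replicate 1 and 1 fatty acid gene without TTg-MI replicate 1 and again without TTg-MI replicate 2.

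Immediate early and heat shock genes, which respond within minutes to stress or handling, were lower in TTg-MI for all 16 measured members, with a median log2 difference of -0.79. The transcription factor genes Atf3 (-2.54, SE 0.69), Nr4a1 (-1.64, SE 0.49), Jun (-0.74, SE 0.18) and Junb (-0.65, SE 0.15) had the smallest p. Ribosomal protein genes were lower for all 11 measured, with a median of -0.30, including Rpl10a (-1.04, SE 0.34), Rps14 (-0.80, SE 0.30), Rpl32 (-0.46, SE 0.15) and Rpl5 (-0.30, SE 0.15). Of 17 cell cycle genes 13 had a lower TTg-MI mean, with a median of -0.19 and with Cdk1 and Bub1 under the lower quartile of every array, among them Mki67 (-0.61, SE 0.27), Mcm6 (-0.39, SE 0.16), Top2a (-0.37, SE 0.16) and Pcna (-0.36, SE 0.17). With Ctrl-MI replicate 1 left out, Atf3, Nr4a1, Rps14 and Mki67 differed by -1.50, -0.95, -0.47 and -0.24. Mki67 differed by -0.97 without Ctrl-MI replicate 2, Pcna by -0.23 without TTg-MI replicate 1, and Rpl10a and Rps14 by -0.56 and -0.52 without TTg-MI replicate 2.

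These 3 lists passed camera with Benjamini-Hochberg at adjusted p of 8.30e-08 for immediate early genes (adjusted p = 0.589 with an estimated correlation), 1.91e-04 for ribosomal proteins (adjusted p = 0.589 with an estimated correlation) and 0.0231 for the cell cycle (adjusted p = 0.603 with an estimated correlation). In limma 0 members passed when adjusted over the list alone and 0 over all genes, and 7, 3 and 0 had an unadjusted p under 0.05. Lower without overlap of the arrays were 9 of 16 immediate early, 6 of 11 ribosomal protein and 7 of 17 cell cycle genes. Higher in that way were 0, 0 and 1. Without Ctrl-MI replicate 1 the medians were -0.26 for immediate early genes, -0.11 for ribosomal proteins and -0.04 for the cell cycle (adjusted p = 0.954 in camera), and without Ctrl-MI replicate 2 they were -1.45 for immediate early genes and -0.39 for the cell cycle, with 13 and 2 members passing over the list alone. Without TTg-MI replicate 1, 1 ribosomal protein gene passed in that way. The cell cycle call also ended without TTg-MI replicate 2 (median -0.18, adjusted p = 0.0933) and with the filter on dim probes (median -0.28, adjusted p = 0.122 in camera with Benjamini-Hochberg), within a range of 2.27e-04 to 0.954 over all alternatives.

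Markers of heart muscle itself did not pass. On every array 6 of the 20 cardiomyocyte and 5 of the 19 sarcomere genes lay within 1 log2 unit of the highest value, which limits the differences they can show. The cardiomyocyte list had a median log2 difference of 0.08 (camera with Benjamini-Hochberg, adjusted p = 0.0995) with the calcium release channel Ryr2 at 0.89 (SE 0.32) and Csrp3 at -0.40 (SE 0.17). The sarcomere list had 0.10 (adjusted p = 0.425), with Myom2 at -0.60 (SE 0.22) and Lmod2 at -0.46 (SE 0.20), and glycolysis 0.14 (adjusted p = 0.378), with Eno3 at 0.68 (SE 0.25) and Pfkm at 0.57 (SE 0.22). Cardiac transcription factors outside the transgene had 0.02 (adjusted p = 0.825), with Tbx20 at -0.91 (SE 0.22) and Prox1 at 1.33 (SE 0.49). Leaving out Ctrl-MI replicate 1 gave 0.45 for Ryr2, -0.25 for Lmod2, 0.35 for Eno3, 0.32 for Pfkm and 0.56 for Prox1. Prox1 differed by 2.10 and Myom2 by -0.39 without Ctrl-MI replicate 2, and Csrp3 by -0.26 without TTg-MI replicate 2. Of these, the cardiomyocyte, sarcomere and glycolysis lists passed camera without Ctrl-MI replicate 2, with medians of 0.22, 0.22 and 0.29, and 5 glycolysis genes and 4 of the transcription factors then passed over the list alone.

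Vessel lists did not pass either. Endothelial markers had a median of -0.05 (camera with Benjamini-Hochberg, adjusted p = 0.692), with Pecam1 at -0.56 (SE 0.19) and Tie1 at 0.69 (SE 0.24). Smooth muscle and pericyte markers had a median of -0.14 and a mean of 0.02 with a downward test (adjusted p = 0.647), with Abcc9 at 1.19 (SE 0.50) and Mustn1 at -0.39 (SE 0.15). Angiogenesis genes had a median of 0.03 (adjusted p = 0.547), with Angpt1, a ligand of the Tek receptor, at 2.03 (SE 0.53) and Hif1a at -1.13 (SE 0.23). With Ctrl-MI replicate 1 left out, Pecam1, Abcc9 and Angpt1 differed by -0.37, 0.43 and 1.27. Abcc9 differed by 1.96 without Ctrl-MI replicate 2 and Tie1 by 0.44 without TTg-MI replicate 1.

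Of the blood cell lists, lymphocyte markers had a median of -0.13 (camera with Benjamini-Hochberg, adjusted p = 0.209), with Cd3g at -0.33 (SE 0.16) and Ms4a1 at -0.32 (SE 0.16). Neutrophil markers had -0.03 (adjusted p = 0.922), with Retnlg at 0.45 (SE 0.24), or 0.75 without TTg-MI replicate 1 and 0.14 without TTg-MI replicate 2. Every measured lymphocyte and neutrophil marker lay under the median of each array, which limits what these lists can show. Epicardial and mesothelial markers had -0.25 (adjusted p = 0.0885), with Upk1b at -0.51 (SE 0.36) and Msln at -0.45 (SE 0.27), or 0.00 and -0.11 without Ctrl-MI replicate 1 and -1.02 and -0.80 without Ctrl-MI replicate 2. They passed on ranks (adjusted p = 0.0382) and without Ctrl-MI replicate 2 (median -0.44), within a range of 8.42e-04 to 0.798 over all alternatives. The p53 and senescence list had -0.15 (adjusted p = 0.129), with Trp53inp1 at -0.53 (SE 0.36, and -0.14 without Ctrl-MI replicate 1, -0.92 without Ctrl-MI replicate 2, -0.15 without TTg-MI replicate 1 and -0.92 without TTg-MI replicate 2), and its member Cdkn1a, an inhibitor of cyclin-dependent kinases, fell by 2.59 (SE 0.54) when adjusted over the list alone (limma with Benjamini-Hochberg, adjusted p = 0.0304). Cdkn1a lost that pass without Ctrl-MI replicate 1 and without Ctrl-MI replicate 2, and its difference was -1.72 without TTg-MI replicate 2. That list passed with the trend and robust prior (adjusted p = 0.0277) and without Ctrl-MI replicate 2 (median -0.38), within a range of 0.0277 to 0.622 over all alternatives.

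Markers of neighbouring tissues and of nerve also did not pass. Several were not shown to be above background. Sftpa1, Scgb1a1, Scgb3a2, Cldn18, Lep, Ucp1, Gfra3, Prph, Myf6 and Mylpf lay under the lower quartile of every array, which limits what these lists can show. Adipocyte markers had a median of -0.04 and a mean of 0.03 with an upward test (camera with Benjamini-Hochberg, adjusted p = 0.692), with Plin1 at 0.22 (SE 0.15). Skeletal muscle markers had a median of -0.03 and a mean of 0.02 with an upward test (adjusted p = 0.838), with Tnnc2 at 0.26 (SE 0.17) and Myh4 at 0.22 (SE 0.16). Lung epithelium had a median of 0.05 (adjusted p = 0.838), with Sftpd at 0.31 (SE 0.16) and Sftpb at -0.20 (SE 0.17), and Schwann and neuronal markers -0.12 (adjusted p = 0.328), with Cdh19 at -0.33 (SE 0.25) and Kcna1 at -0.22 (SE 0.17). Single arrays moved 5 of these genes by more than 1.5 times, Tnnc2 to 0.12, Cdh19 to 0.00 and Kcna1 to -0.07 without TTg-MI replicate 1, Myh4 to 0.13 without Ctrl-MI replicate 2, and Sftpb to -0.09 without Ctrl-MI replicate 1.

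The circadian clock list had a median of 0.00 (camera with Benjamini-Hochberg, adjusted p = 0.825), with Bhlhe41 at -0.56 (SE 0.41, and -0.01 without TTg-MI replicate 1) and Cry1 at 0.19 (SE 0.15). Its median was 0.75 without TTg-MI replicate 1 and -0.76 without TTg-MI replicate 2, and it passed in both fits, with opposite directions and with 6 and 4 members passing over the list alone.

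Zfp931 lay in a run of neighbouring zinc finger genes on chromosome 2 that was noticed after the values were seen. A run was counted as adjacent named genes that each differed at least 1.5-fold in the same direction at an unadjusted limma p under 0.05. All 18 named genes of this one, 5 with Zfp and 13 with Gm symbols, had both TTg-MI arrays above both Ctrl-MI arrays, with differences of 0.84 to 2.14 and a median of 1.09, or 2.13-fold. All 18 were also higher on Ctrl-MI replicate 2 than on Ctrl-MI replicate 1, by a median of 0.638. The next longest such run in the genome held 3 genes. In 1000 random orders of the genes the longest run held 5, a permutation p of 0.001, which is the smallest these permutations can give. Random orders treat genes as independent, which neighbours of 1 family may not be. The p speaks to their grouping along the chromosome and not to a difference between the genotypes. None of the 18 passed limma over all probes.

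**Figure D3:**
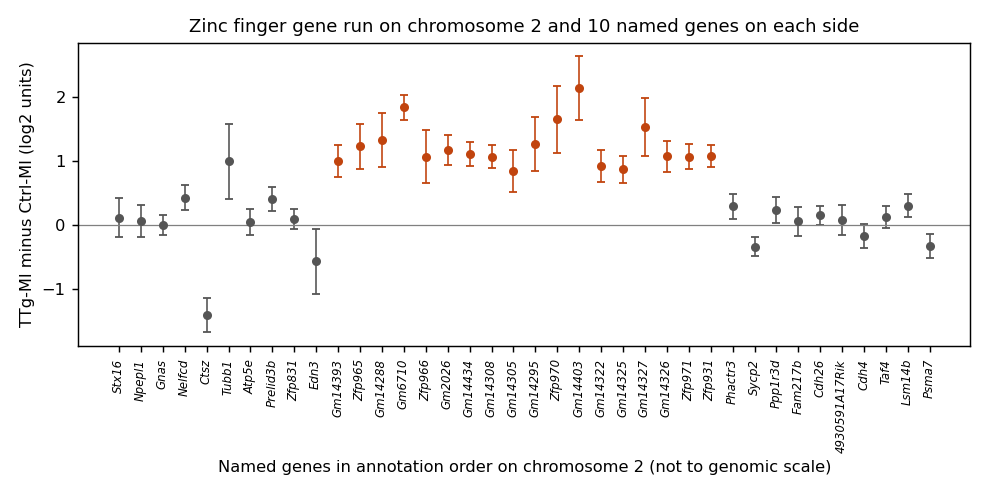
Log2 difference between TTg-MI and Ctrl-MI for the 18 genes of the chromosome 2 run (orange) and the 10 named genes on each side (grey), in annotation order and not to genomic scale. Points are differences of group means (n = 2 each) and bars are standard errors from limma. The run's genes lie between 0.84 and 2.14.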

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

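Bmp10 passed in every limma fit of its own value, with adjusted p (Benjamini-Hochberg) of 2.45e-05 to 0.0239. Quantile normalization and median centring each left 1 gene and 17 lists. The removal of atrial genes took out the atrial list itself, and all 33 lists then tested kept their result, 17 of them called. The other groupings of the arrays and the removal of atrial genes were chosen after the data had been seen. Genes called in limma with Benjamini-Hochberg numbered 4 with a trend and robust prior (Bmp10, Jchain, Resf1 and Gabra3). Without adjustment, 1130 probes had a limma p under 0.05 and differed at least 1.5-fold. An ordinary linear model called 0 genes after Benjamini-Hochberg adjustment and gave 1241 probes at an unadjusted p under 0.05. Genes called in limma ranged from 1 to 332 when single arrays were left out, and the number at an unadjusted p under 0.05 ranged from 862 to 3275. The filter on dim probes, under which fewer probes were tested, left 1135 such probes. The lists called numbered 0 with an estimated correlation, 0 by directional fry and 1 by mixed fry, and 15 to 22 when single arrays were left out. Splitting the arrays by replicate number gave 0 genes, 866 probes at an unadjusted p under 0.05 and 23 lists, 17 of them among the 18 of the real comparison, and setting Ctrl-MI replicate 1 and TTg-MI replicate 2 against the others gave 0 genes, 479 probes and 2 lists. The atrial median ranged from -0.46 to 3.35 and the circadian median from -0.76 to 0.75 as single arrays were left out. Both reversed, the atrial list without Ctrl-MI replicate 2 and the circadian list without TTg-MI replicate 1. For these and the other changed counts the cause was not tested. Among 1554 alternative values of single genes and lists, 20 others changed sign, all without a call in either setting.

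The replicate numbers in the titles were not treated as pairing. The correlation of the replicate differences of the groups was 0.163, which with only 2 pairs cannot exclude an effect shared by replicate number. The split by replicate number called 23 lists, 17 of them among the 18 of the real comparison. A replicate block gave 7 genes (Bmp10, Jchain, Frzb, Sfrp2, Sfrp1, Meox1 and 1 unnamed probe), 19 lists, 2465 probes at an unadjusted p under 0.05 and 4 of the 5 factor genes.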

Other observations

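All tests in this part were chosen after the result was seen, except those of zinc finger genes elsewhere in the genome and of shared signal, which were written down first. The criterion for the sinoatrial panel was made stricter after 2 of its genes had been seen to be higher. Genes named here were chosen after their values were seen.

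Clock genes differed between the TTg-MI hearts, as a set of values with no comparison behind them. Dbp, an output gene of the circadian clock, stood at 12.99 on TTg-MI replicate 1 and 18.20 on TTg-MI replicate 2, while the Ctrl-MI arrays differed by 0.27. Other clock genes differed between the Ctrl-MI arrays too, replicate 1 against 2, with Per1 at 0.88, Ciart at -0.84, Nr1d1 at -0.97 and Npas2 at -1.46. Per1 was lower on TTg-MI replicate 1 by -3.57 and Ciart by -3.35, whereas Arntl, which peaks in the opposite phase, was higher there by 2.81. Time of collection was not used here.

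Hamp, which encodes the iron hormone hepcidin, differed by 1.49 (SE 0.43), its paralog Hamp2 by 0.77 (SE 0.29) and Corin, the protease that activates natriuretic peptides, by 1.41 (SE 0.35), each without overlap of the arrays, while the arrays overlapped for Nppb at -2.34 (SE 1.19). Replicate 1 differed from replicate 2 by 1.05 for Hamp and -1.03 for Corin in Ctrl-MI, and by 0.71 for Hamp2 in TTg-MI. Of 9 further atrial genes outside the fixed atrial list, 5 were higher without overlap, Tbx5, itself a factor of the transgene, at 2.45 (SE 0.33), Kcnj3 at 1.64 (SE 0.37), Sbk3 at 1.02 (SE 0.33), Sbk2 at 0.93 (SE 0.19) and Kcnj5 at 0.84 (SE 0.18), and Nr2f1 was lower at -0.45 (SE 0.15). None passed limma over all probes. Of 7 plasma cell genes, 4 were lower and 1 higher without overlap of the arrays: Jchain differed by -2.63, Sdc1 by -0.55, Xbp1 by -0.23, Mzb1 by -0.13 and Derl3 by 0.30, with Mzb1 under the lower quartile on TTg-MI replicate 1. Around Resf1, at -3.69, the silencing genes Setdb1 and Zfp809 differed by -0.41 and -0.53, and Trim28, Morc2a and Apobec3 by 0.23, 0.05 and 0.97. The Ctrl-MI arrays themselves, replicate 1 against 2, differed by 0.78 for Setdb1 and -0.70 for Zfp809.

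Bmp10 and other atrial genes were higher in TTg-MI, and tissue taken with the sample is a candidate explanation beside the transgene. A surplus of tissue holding the sinoatrial node would raise 7 measured panel genes, Shox2, Hcn4, Tbx3, Isl1, Vsnl1, Rgs6 and Tbx18. Their median difference was 0.0452, with 2 of 7 higher without overlap (one-sided exact binomial p = 0.330). Shox2, 1 of those 2, and Vsnl1 lay under the lower quartile of every array, so this stays open. The panel cannot tell about right atrial muscle taken without the node. A surplus of atrial tissue of either side would place both TTg-MI arrays above both Ctrl-MI arrays for Myl4, Sln and Myl7, but the lower TTg-MI array lay at -1.38, -1.01 and 1.02 relative to Ctrl-MI replicate 1, which neither shows nor excludes it. Of the 3 splits of the 4 arrays, 1, the real one, gave as many genes, 1 against at most 0 for the others, and 3 splits are too few for a share under 0.05. An effect of the factors on Bmp10 remains an untested hypothesis.

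Matrix, fibroblast and macrophage lists were lower in TTg-MI. Ctrl-MI replicate 1 alone may be the source. Without it the matrix median was still -0.585, beyond the 0.408 that the SD of the TTg-MI scores gives for 1 array against their mean. That SD rests on 2 arrays and 1 Ctrl-MI array remains, so this cannot tell whether Ctrl-MI replicate 1 was the whole cause. A lower share of all non-muscle cells would lower endothelial, smooth muscle and pericyte genes as much as fibroblast genes. The endothelial score lay above the resting fibroblast score by 0.715 (SE 0.169, 2 arrays per group), which argues against an equal fall. The resting fibroblast list had already been seen to be lower, which favours such a gap. Smooth muscle and pericyte markers had a median of -0.14, with list scores lower in TTg-MI without overlap. A smaller fall shared by these cells stays open. Of the 3 splits of the 4 arrays, 2, the real one included, gave as many lists, 18 for the real one and 23 for replicates 1 against replicates 2, which shared 17 of the 18, and 3 splits are too few for a share under 0.05. A smaller scar, a difference in the part sampled and an effect of the transgene on fibroblasts stay open and untested.

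The run of zinc finger genes on chromosome 2 may reflect a local difference. A genome-wide change of Zfp genes was argued against, as 353 of them elsewhere had a median of 0.0564 (SE over genes 0.0176). Genes with Gm symbols, 13 of the run's 18, were not part of that comparison. The 10 genes on each side had a median of 0.0823 (SE over genes 0.132), which argues against a rise reaching beyond the family. These SEs treat genes as independent and do not measure the spread between hearts. A regional difference of mixed direction stays open, as flanking genes included Ctsz at -1.41 (SE 0.27) and Nelfcd at 0.42 (SE 0.19). Signal shared between near-identical genes stays open, since the run's differences between the Ctrl-MI arrays had a median of 0.638 (replicate 2 minus 1) and an SD of 0.441 against a median of 0.574 in random sets (0.157 of sets as alike), and 9 higher probes of the chromosome held values identical to another probe. A strain difference linked to the transgene was not tested.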
